A study of Mus musculus with 6 samples.

How the data were processed

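Splenic CD8 T cells of female C57BL/6 mice, WT or Utx KO, were studied with 3 biological replicates per genotype. Per the labels' protocols, naive cells were enriched with a CD8 isolation kit and an anti-CD44 antibody, and cells were stimulated with plate-bound antibodies to TCR-beta (3 µg/ml) and CD28 (1 µg/ml) for 2 days with interleukin 2 (10 ng/ml), followed by 3 days in interleukin 2. Total RNA (500 ng) went into QuantSeq 3' mRNA libraries. The labels call the samples biological replicates but do not say whether these are separate animals, so p-values measure the spread between these 3 samples per group.

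The authors deposited 1 table per library with a CPM value for each of 25655 Ensembl gene identifiers, that is, reads of a gene scaled to the same total over the listed genes in each library, per the file headers and the column totals. The submitters' processing notes name the builds GRCm38 and mm10. The aligner, the counting tool, its treatment of strand and of reads with several matches, and any filters are not given in the sources used here. Dividing each library's deposited CPM values by the value of a single read gave whole reads for 100% of the values above 0 (tolerance 0.001 reads), with totals of 1619085 to 2529113 reads per library. At these depths 3 reads, the limit that a count of 0 allows, correspond to 1.19, 1.38 and 1.64 CPM in WT and 1.19, 1.71 and 1.85 CPM in Utx KO replicates 1, 2 and 3. A 3' end library counts about 1 tag per transcript, so gene length does not scale the values, and changes in the use of transcript ends can alter them. Symbols were found for 25600 of 25655 identifiers in the supplied name table; 55 had none. Coordinates and exon overlaps come from GENCODE mouse release M21 (GRCm38), which covers 10580 of the tested genes.

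Because the deposited values are CPM and not counts, the main test was limma-trend (limma 3.58.1 in R 4.3.3, robust = FALSE) on log2(CPM + 1), with genotype as the only term, over the 10590 genes with at least 1 CPM in 3 or more libraries. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and tests were two-sided. Fold changes are on the log2(CPM + 1) scale, which understates changes of low genes. The plan made before the data were examined had named edgeR's quasi-likelihood test for counts and this limma test for normalized values. It had named camera on log2 CPM from edgeR, and camera was run instead on the same log2(CPM + 1) values. The edgeR test (edgeR 4.0.16, TMM factors, filterByExpr) on the recovered reads tested 8832 genes and called 1106 (546 up, 560 down). It and the other count tests serve as alternatives only.

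Gene lists for activated CD8 T cells and for other cell types in the spleen, 25 in all, were fixed before the data were examined. The 21 with at least 5 tested members were compared with all other tested genes by camera with a preset inter-gene correlation of 0.01 and adjusted together, and camera was repeated with an estimated correlation. The lists share members, such as Prf1 and Gzmb (cytotoxic molecules and interleukin 2 response), so their tests are not independent. Further gene families were chosen after the values were seen and appear only in the closing observations. For genes with 1 to 3 pooled reads in a group, the ratio of pooled CPM is given with an exact conditional binomial interval (95%).

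Named genes follow a rule set before the data were examined. It takes Kdm6a, Kdm6b and Uty; the 12 largest rises and 12 largest falls among genes with an adjusted p under 0.05, a mean of at least 10 CPM in the higher group and no overlap between the groups; up to 4 members of each tested list with the lowest adjusted p; and a fixed set whatever their result, of which Gzmb, Prf1, Ifng, Tnf, Il2, Tcf7, Ccr7, Il7r, Tbx21, Eomes, Prdm1, Pdcd1 and Cxcr3 are reported here. Genes known only by a model number (21 of the changed genes) and receptor segments are counted, not named. The single cell-type markers outside this rule, the T-cell receptor constant genes and, in the closing observations, gene families and the neighbouring copy of Gvin1 were chosen after their values were seen.

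Reads of similar or overlapping genes cannot be separated here. Of 111 named genes that were measured, 13 share exon sequence with another gene on the same strand and 32 on the opposite strand. All 50-nt pieces of the last 300 nt of each named gene's protein-coding transcripts were searched in the transcripts of all other genes. For 12 named genes at least 20% of the pieces occurred elsewhere: Gvin1, Fdps, Atp5g2, Il2, S100a4, Dnaja1, Hsp90aa1, Gbp4, Ly6c2, Gpi1, Naa60 and Klrc2. Values of these genes are uncertain to that extent.

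Limma-trend (also with a replicate block), edgeR, DESeq2 and limma-voom were tried on simulated counts. These had the means and library sizes of these libraries and 200 genes changed by known folds. Camera with the preset correlation was tried on such counts too. Other tests were not, among them camera with an estimated correlation and fry. For Utx KO against WT, limma-trend on 10602 simulated genes recovered 40% of the genes changed 1.5-fold, 66% of those changed 2-fold and 93.9% of those changed 4-fold, with 3.95% false calls. Alternatives were other scalings, other filters, DESeq2 (version 1.42.0), limma-voom and edgeR on the recovered reads, a pseudocount of 0.1, a replicate block, leaving out each library in turn, stricter thresholds, and fry for the lists. The lists under count tests were compared by camera on the ranked test statistics.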

Results

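The series profiled messenger RNA in cultured CD8 T cells from the spleens of female C57BL/6 mice labelled as wild type (WT) or as a knockout of Utx, the H3K27 demethylase encoded by Kdm6a (Utx KO). Naive cells were activated through the T-cell receptor and CD28 for 2 days with interleukin 2, then kept in interleukin 2 alone for 3 days. Each genotype had 3 biological replicates, so 6 libraries were compared at day 5, and the question was how activated CD8 T cells labelled Utx KO differ in expression from WT cells. Libraries were made with a kit that reads the 3' end of each polyadenylated transcript. The values are read counts scaled to the same total in each library (CPM), from which the whole read counts could be recovered. Recovered totals were 2529113, 2170122 and 1827703 reads in WT replicates 1, 2 and 3, and 2517655, 1750802 and 1619085 reads in Utx KO replicates 1, 2 and 3. A gene with no read in a library could therefore still lie at up to 1.19 CPM in the deepest Utx KO library and up to 1.85 CPM in the shallowest (3 reads of the total). Such floors, and the count intervals given for single genes, cover counting error only.

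Libraries of a genotype resembled each other more than libraries of different genotypes. Pearson's r of log2(CPM + 1) over 10590 genes was 0.977 to 0.980 among WT libraries, 0.974 to 0.977 among Utx KO libraries and 0.959 to 0.967 between genotypes. These correlations run across genes, which are not independent replicates. The first principal component held 41.7% of the variance and separated the genotypes. No pair of replicates held identical values or differed by as little as sampling noise (chi-square per degree of freedom 1.33 to 2.06), so all 6 libraries were kept.

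The targeted gene was lower but not absent in the knockout libraries. Kdm6a (ENSMUSG00000037369, chromosome X, 18162575 to 18279936 in GRCm38) was at 44.3, 49.3 and 53.6 CPM in WT replicates 1, 2 and 3, and at 27.8, 39.4 and 31.5 CPM in Utx KO replicates 1, 2 and 3. The log2 fold change was −0.57 (SE 0.15, limma adjusted p = 0.0123), with each Utx KO library below each WT library. The sources used here do not state which part of the gene is deleted, and a 3' tag outside that part checks nothing, so this value does not settle the labels. Over 19 alternative settings the adjusted p ran from 0.0056 to 0.0708. It was above the threshold with DESeq2 (0.0708) and without WT replicate 2 (0.0528), WT replicate 3 (0.0708) or Utx KO replicate 1 (0.0554). The paralog Kdm6b, a demethylase of the same histone mark, was at 21.9 ± 3.64 CPM in WT and 30.5 ± 10.2 CPM in Utx KO (SD, n = 3, limma adjusted p = 0.211). The Y-linked paralog Uty was listed at 0 in all 6 libraries, as were Ddx3y, Eif2s3y and Kdm5d; the labels give the mice as female. In the list of 23 tested H3K4 and H3K27 modifiers, 0 rose and 2 fell, Kdm6a and Jarid2, a subunit of Polycomb repressive complex 2 (camera adjusted p = 0.606). Jarid2 had a log2 fold change of −0.33, and its call was lost without WT replicate 2 or 3 and with DESeq2 (limma or DESeq2 adjusted p up to 0.0920 over the alternatives).

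Utx KO cells carried less RNA for granzymes A, B and K, perforin, interferon gamma and the chemokine receptors Ccr2, Cxcr3 and Cxcr6 than WT cells. Of 52 tested interferon-stimulated genes, 22 fell, although as a list they had an adjusted p = 0.0554 with an estimated correlation. Genes of naive and memory-precursor T cells moved both ways: 13 of 28 rose, among them Lef1 and Satb1, and 4 fell, with the largest changes of the list in Dapl1 and Ly6c2, which fell (as a list, adjusted p = 0.338 with an estimated correlation). Granzyme A (Gzma) showed the largest fall by the naming rule, from 199 ± 22.5 CPM in WT to 4.57 ± 1.28 CPM in Utx KO (SD, n = 3). Igfbp4, which encodes a secreted binding protein of insulin-like growth factors, rose from 73.3 ± 5.26 to 369 ± 24.6 CPM. Of 10590 genes tested with limma, 1142 changed at an adjusted p under 0.05, of which 559 rose and 583 fell in Utx KO. A change of at least 2-fold was fitted for 317 of these, 143 up and 174 down; with DESeq2 it was 195, 74 up and 121 down. Groups did not overlap for 2809 genes, 26.5% of those tested, where chance gives 10%. Of the 1142 changed genes, 1121 had groups that did not overlap. The count of changed genes moved by over 1.5 times with DESeq2 on the recovered reads (595) and without WT replicate 2 (754). The plot of fold change against expression shows these calls.

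**Figure D1:**
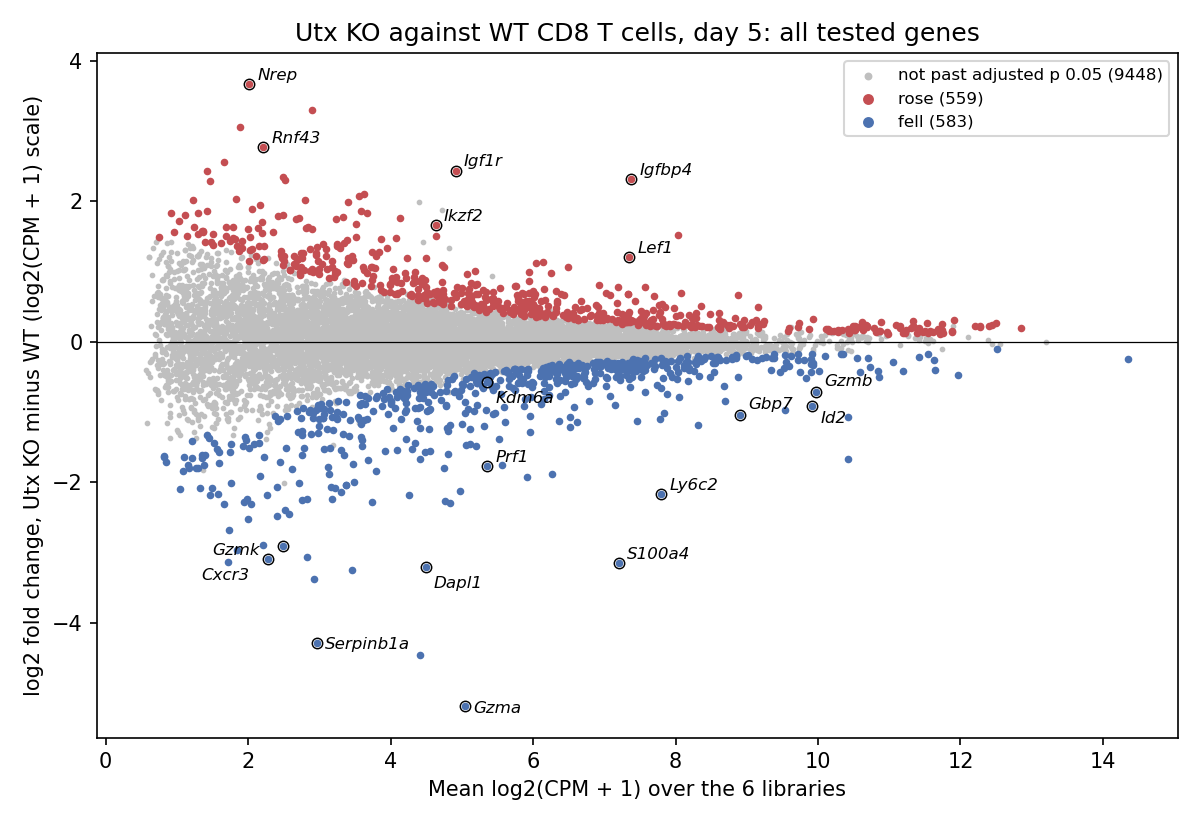
Log2 fold change of Utx KO minus WT (y axis, log2(CPM + 1) scale) against the mean log2(CPM + 1) over 6 libraries (x axis), each point a tested gene. Red points are the 559 genes that rose and blue points the 583 that fell; circles mark named genes, with Gzma lowest at −5.19 and Nrep highest at 3.67.

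Of the 12 largest falls by the naming rule, Gzma and Gzmk are in the cytotoxic list and Cxcr3 in that of chemokine receptors. After Gzma (chromosome 13, 113093825 to 113100981, log2 fold change −5.19, SE 0.17, limma adjusted p = 7.64e-17) came Gvin1, a fall of uncertain size, and Serpinb1a, an inhibitor of neutrophil-type serine proteases, which fell from 33.6 ± 5.01 to 0.793 ± 0.346 CPM (SD, n = 3). Dapl1 fell from 67.1 ± 3.05 to 6.51 ± 1.36 CPM. S100a4, a calcium-binding protein of activated and migrating cells, fell from 438 ± 18 to 49.8 ± 13.9 CPM, although 54.6% of its 3' end sequence is shared with an overlapping gene model. The chemokine receptor Cxcr3 fell from 13.2 ± 1.40 to 0.894 ± 1.22 CPM and granzyme K (Gzmk) from 14.5 ± 2.36 to 1.06 ± 0.232 CPM. The other falls of that size were Ncf1, Rgs18, Apobr, Golm1 and Abcb1a, with log2 fold changes from −3.37 to −2.39. Gvin1 (−4.46, limma adjusted p = 2.77e-05) shares its whole 3' end with a neighbouring copy, varied from 12 to 357 CPM among WT libraries and lost its call with limma-voom (adjusted p = 0.152, the highest of 19 alternatives that reached down to 1.34e-14). With a pseudocount of 0.1 the log2 fold changes of Cxcr3 and Apobr were over 1.5 times larger, at −4.75 and −4.45.

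Among the largest rises, the insulin-like growth factor receptor Igf1r went from 12.2 ± 2.88 to 69.2 ± 5.98 CPM (SD, n = 3; log2 fold change 2.44, limma adjusted p = 2.85e-10), alongside Igfbp4 (2.32, SE 0.08). Rnf43, a ubiquitin ligase that removes Wnt receptors from the cell surface, rose from 0.782 ± 0.317 to 11.1 ± 0.806 CPM. Nrep was at 13.6 ± 2.88 CPM in Utx KO and had 1 read in all WT libraries together, against 81 in Utx KO. The ratio of its pooled CPM was 89.8 (exact 95% counting interval 15.7 to 3590), and its log2 fold change of 3.67 became 6.35 with DESeq2. Cd24a, Wdfy1, Rarg, Maml3, Slc25a23, Sox4 and Frat2 rose with log2 fold changes from 2.35 to 1.86; of these, Rarg encodes a retinoic acid receptor, Maml3 a coactivator of Notch signalling and Sox4 a transcription factor. Naa60 was at 12.7, 0 and 0 CPM in the WT libraries and at 22.4 ± 0.914 CPM in Utx KO. It overlaps other genes on both strands, its log2 fold change ran from 2.20 with edgeR to 5.48 with a pseudocount of 0.1, and its call was lost with DESeq2 (adjusted p = 0.763; lowest of 19 alternatives 7.72e-11).

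Genes of the cytotoxic effector list were lower as a group. Of 14 tested cytotoxic effector genes, 11 fell and 1 rose, and adjusted over the list alone the counts were also 11 and 1. Perforin (Prf1), which forms pores in target cells, fell from 74.7 ± 3.62 to 21.4 ± 4.30 CPM and granzyme B (Gzmb) from 1283 ± 58.2 to 785 ± 104 CPM (SD, n = 3). Their log2 fold changes were −1.77 (SE 0.15, limma adjusted p = 9.02e-09) and −0.72 (SE 0.06, limma adjusted p = 1.79e-08). Serpinb9, an inhibitor of granzyme B, is in this list too and among the 11 falls (−1.28), so that count does not cover killing molecules alone. The median log2 fold change of the list was −0.89 (camera adjusted p = 2.2e-17 with the preset correlation, and adjusted p = 0.0150 with an estimated correlation). It was the only list of the 21 tested whose call held with an estimated correlation.

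Cytokine and chemokine genes gave 4 falls and 1 rise among 15 tested members, with the same counts adjusted over the list alone. Interferon gamma (Ifng) fell from 7.82 ± 1.56 to 1.32 ± 0.236 CPM (SD, n = 3; log2 fold change −1.91, limma adjusted p = 0.000527), and the chemokine Ccl5 from 12.4 ± 3.06 to 2.57 ± 1.92 CPM. Interleukin 10 (Il10), a cytokine that restrains inflammation, fell from 34 pooled reads in WT to 2 in Utx KO, a CPM ratio of 0.0652 (exact 95% counting interval 0.00759 to 0.254). Lymphotoxin alpha (Lta) fell by 0.38 on the log2 scale, a call lost without Utx KO replicate 3 (−0.22, adjusted p = 0.111) and with DESeq2 (adjusted p = 0.317), where the lowest of 19 alternatives was 5.51e-05. Tnf (22.5 ± 6.04 and 16.9 ± 4.64 CPM in WT and Utx KO) and Il2 (2.51 ± 2.03 and 2.69 ± 0.791 CPM) did not pass, with limma adjusted p of 0.331 and 0.822. The sign of Il2 turned without WT replicate 3, at −0.26. The list was called lower with the preset correlation (camera adjusted p = 0.00568) but not with an estimated correlation (adjusted p = 0.326) or with the stricter filter on low values (adjusted p = 0.0791).

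Interferon-stimulated genes, which encode antiviral proteins, gave 22 falls and 0 rises among 52 tested members. Adjusted over the list alone, 29 fell and 1 rose. Gbp7 fell from 688 ± 14.2 to 333 ± 6.02 CPM and Isg20, an antiviral exonuclease, from 85.8 ± 2.70 to 24.8 ± 1.75 CPM (SD, n = 3). Their log2 fold changes were −1.04 (SE 0.05) and −1.75 (SE 0.13), with limma adjusted p of 4.31e-13 and 4.08e-10. Other interferon-induced GTPases, Gbp4 (−1.15) and Gbp2 (−0.89), also fell; 26.0% of the 3' end sequence of Gbp4 is shared with other family members, so its reads could be split among them. The median log2 fold change was −0.41 and 42 of 52 members were lower in Utx KO (camera adjusted p = 1.15e-14 with the preset correlation, and adjusted p = 0.0554 with an estimated correlation).

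Chemokine receptors and adhesion molecules, which guide T cells into tissue, gave 13 falls and 4 rises among 22 tested members, again with the same counts adjusted over the list alone. Ccr2 fell from 326 ± 28.9 to 161 ± 19.5 CPM and Cxcr6 from 61.0 ± 9.77 to 21.6 ± 5.86 CPM (SD, n = 3). Their log2 fold changes were −1.02 and −1.48 (limma adjusted p of 4.86e-09 and 2.69e-06). The integrin chain Itga4 fell from 21.3 ± 0.936 to 4.64 ± 0.815 CPM. In the other direction, the lymph-node homing receptor Ccr7 rose from 119 ± 7.12 to 175 ± 4.30 CPM (log2 fold change 0.56, limma adjusted p = 3.44e-05). The list was called lower with a camera adjusted p of 1.11e-05, and had an adjusted p = 0.0554 with an estimated correlation.

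**Figure D2:**
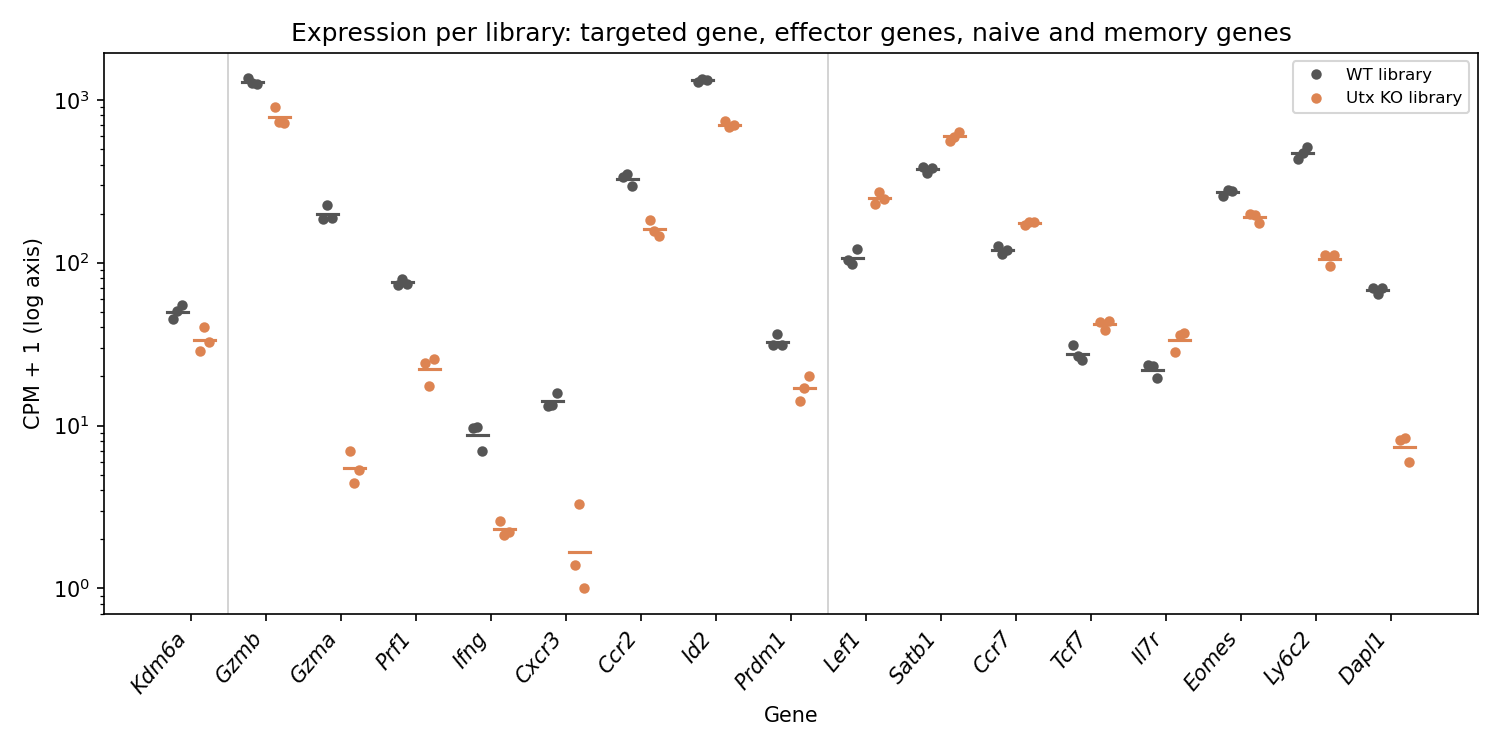
CPM + 1 (y axis, log scale) of Kdm6a, 8 effector or chemokine receptor genes that fell and 8 members of the naive and memory list (x axis) in 3 WT libraries (grey) and 3 Utx KO libraries (orange); each point is a library and each line the mean of log2(CPM + 1) in a group. Gzma separates furthest, at 184 to 225 CPM in WT and 3.43 to 5.96 CPM in Utx KO, and of the 8 naive and memory genes 5 lie higher and 3 (Eomes, Ly6c2 and Dapl1) lower in Utx KO.

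Naive and memory-precursor genes moved in both directions, with 13 rises and 4 falls among 28 tested members. Adjusted over the list alone, 13 rose and 7 fell. Lef1, a transcription factor of naive and memory T cells, rose from 107 ± 11.6 to 248 ± 21 CPM (SD, n = 3; log2 fold change 1.21, SE 0.09, limma adjusted p = 4.1e-10). Its relative Tcf7 rose from 26.6 ± 3.07 to 40.9 ± 2.81 CPM (0.60, limma adjusted p = 0.00944; above the threshold only with DESeq2, 0.0846, the lowest of 19 alternatives being 0.00612). The chromatin organiser Satb1 rose from 374 ± 17.0 to 594 ± 38.3 CPM. Il7r, the receptor chain for interleukin 7, rose from 21.1 ± 2.16 to 32.7 ± 4.60 CPM, but its call (limma adjusted p = 0.0232) was lost with DESeq2 (0.164) and without WT replicate 2 (0.0505), WT replicate 3 (0.0942), Utx KO replicate 2 (0.0977) or Utx KO replicate 3 (0.0974), against a lowest value of 0.0129 over 19 alternatives. The strongest changes of the list were falls, of Dapl1 (−3.20) and of Ly6c2 (471 ± 38.4 to 105 ± 9.09 CPM), a surface protein of memory and effector CD8 T cells that shares 23.3% of its 3' end sequence with relatives. The camera adjusted p was 0.0298 (higher) with the preset correlation, but the adjusted p = 0.338 with an estimated correlation. It was also above the threshold with the stricter filter (0.0665), with DESeq2 statistics (0.112), without Utx KO replicate 2 (0.0845) and without Utx KO replicate 3 (0.0652).

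Transcription factors of effector cells gave 6 falls and 3 rises among 21 tested members, or 7 falls and 4 rises adjusted over the list alone. Id2, which promotes effector differentiation, fell from 1321 ± 30 to 702 ± 30.3 CPM (SD, n = 3; log2 fold change −0.91, SE 0.05, limma adjusted p = 4.12e-13). Maf fell from 58.6 ± 8.33 to 11.7 ± 3.25 CPM, Hopx from 62.1 ± 6.53 to 30.1 ± 1.46 CPM and Prdm1 (Blimp-1) from 31.9 ± 3.12 to 16.1 ± 3.02 CPM. Eomes, which belongs to the naive and memory list and not to this one, fell from 269 ± 11.1 to 189 ± 13.3 CPM. T-bet (Tbx21) was at 23.1 ± 1.12 and 27.6 ± 5.85 CPM (limma adjusted p = 0.519). Ikzf2 (Helios) rose from 13 ± 1.16 to 43.1 ± 3.08 CPM. The list was called lower (camera adjusted p = 0.0123) but not with an estimated correlation (adjusted p = 0.134).

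Inhibitory receptors and exhaustion-associated genes split, with 4 rises and 6 falls among 18 tested members (5 and 8 adjusted over the list alone), and the list was not called (camera adjusted p = 0.220). Cd160 fell from 28.4 ± 2.38 to 5.46 ± 2.84 CPM (SD, n = 3) and Entpd1 (CD39) from 19.4 ± 2.20 to 6.27 ± 0.0899 CPM. Havcr2 (TIM-3) fell from 33 pooled reads to 3, a CPM ratio of 0.101 (exact 95% counting interval 0.0198 to 0.321), and its log2 fold change of −2.17 became −4.38 with a pseudocount of 0.1. Tox, a transcription factor of exhausted T cells, rose from 15.5 ± 2.73 to 29.6 ± 5.5 CPM. PD-1 (Pdcd1) was at 4.46 ± 1.33 and 1.70 ± 1.08 CPM and did not pass (limma adjusted p = 0.0982). Receptors shared with natural killer cells gave 1 rise and 2 falls among 10 tested members (2 and 3 adjusted over the list alone; camera adjusted p = 0.170). Klrk1 (NKG2D) fell by 0.92 on the log2 scale, Klrd1 was at 58.4 ± 7.25 and 45.7 ± 3.14 CPM (limma adjusted p = 0.0950), and Klrc2 rose by 1.13. The rise of Klrc2 was lost without Utx KO replicate 2 (adjusted p = 0.101; lowest of 19 alternatives 0.00194), and 20.1% of its 3' end sequence is shared with Klrc1 and Klrc3.

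Genes of the amino acid and integrated stress response gave 8 rises and 1 fall among 33 tested members (12 and 1 adjusted over the list alone), and 27 of the 33 were higher in Utx KO. Ddit4 rose from 213 ± 39.0 to 347 ± 73.3 CPM, Ddit3 (CHOP) from 40.9 ± 10.5 to 71.0 ± 12.7 CPM and the seryl-tRNA synthetase Sars from 443 ± 7.95 to 553 ± 7.91 CPM (SD, n = 3). The rise of Ddit4 (limma adjusted p = 0.000197) was lost with DESeq2 (0.0627; lowest of 19 alternatives 5.55e-07). The amino acid transporter Slc7a5 went the other way, from 138 ± 10.3 to 59.0 ± 4.05 CPM (log2 fold change −1.22, limma adjusted p = 4.8e-09). Glycolytic and hypoxia-responsive genes gave 9 rises and 0 falls among 36 (14 and 1 adjusted over the list alone). Egln3, an oxygen-sensing prolyl hydroxylase, rose from 194 ± 12.4 to 274 ± 18.6 CPM, and Gpi1, Ndrg1 and Slc2a3 rose by 0.27, 0.37 and 0.33 on the log2 scale. Camera called both lists higher (adjusted p = 0.00116 and 0.00257), and neither with an estimated correlation (adjusted p = 0.131 and adjusted p = 0.228).

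Genes of the list oxidative phosphorylation, nuclear-encoded gave 4 rises and 1 fall among 75 (3 and 1 adjusted over the list alone), with a median log2 fold change of 0.05. Atp5g2, a subunit of the ATP synthase, rose from 453 ± 11.5 to 526 ± 10.4 CPM (SD, n = 3), a call lost without WT replicate 1 (adjusted p = 0.0527; lowest of 19 alternatives 0.00312), and 55.5% of its 3' end sequence occurs in other gene models. The list was at the threshold (camera adjusted p = 0.0449), had an adjusted p = 0.527 with an estimated correlation, and was above the threshold without WT replicate 1 (0.128), WT replicate 2 (0.0509) or Utx KO replicate 1 (0.374) and in 4 further refits given with the alternatives. The share of reads from mitochondrially encoded genes was 2.27% ± 0.219 in WT and 1.71% ± 0.155 in Utx KO, and that of ribosomal protein genes 16% ± 0.150 and 17.6% ± 0.372 (SD, n = 3). Each gave an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allow.

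Of 38 S-phase genes, 5 fell and 1 rose (8 and 1 adjusted over the list alone), and 29 were lower in Utx KO. The replication checkpoint gene Clspn fell from 201 ± 11.6 to 150 ± 4.55 CPM and Pcna, the sliding clamp of DNA polymerase, from 341 ± 4.75 to 281 ± 20.6 CPM (SD, n = 3). Camera called the S-phase list lower (adjusted p = 0.000566), with an adjusted p = 0.0554 with an estimated correlation. Of 40 G2 and M-phase genes, 2 rose and 2 fell, also when adjusted over the list alone, among them the mitotic kinase Plk1 (log2 fold change 0.42), and the list was not called (camera adjusted p = 0.439).

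T-cell receptor and costimulatory genes gave 8 rises and 5 falls among 32 (11 and 7 adjusted over the list alone; camera adjusted p = 0.127). Tnfrsf4 (OX40) rose from 8.69 ± 1.91 to 31.5 ± 2.93 CPM, and Cd5 and Cd6, which dampen receptor signals, rose from 24.6 ± 1.53 to 50.8 ± 5.97 CPM and from 17.3 ± 3.53 to 37.7 ± 3.81 CPM (SD, n = 3). The NF-kappa-B inhibitor Nfkbia rose by 0.67 on the log2 scale. Genes of interleukin 2 signalling gave 6 rises and 8 falls among 24, also when adjusted over the list alone, with Il2ra (CD25) up from 501 ± 15.4 to 622 ± 4.30 CPM (camera adjusted p = 0.224). Regulators of p53 and apoptosis gave 1 rise and 3 falls among 26, also when adjusted over the list alone (camera adjusted p = 0.504). The pro-apoptotic Bbc3 (PUMA) rose from 6.14 ± 3.25 to 23.0 ± 2.90 CPM, and Fasl and Bcl2l11 (BIM) fell by 1.18 and 0.59. Heat shock genes gave 1 rise and 4 falls among 23 (1 and 5 adjusted over the list alone; camera adjusted p = 0.0617). The cytosolic chaperones parted, with Hsp90ab1 up by 0.20 and Hsp90aa1 down by 0.17 on the log2 scale, though 37.6% of the 3' end sequence of Hsp90aa1 is shared with other gene models. Cholesterol genes gave 1 rise and 0 falls among 24 and 0 when adjusted over the list alone (camera adjusted p = 0.850), the rise being Fdps (log2 fold change 0.22), whose 3' end is mostly shared with other gene models. That call was lost without WT replicate 1 (adjusted p = 0.113), WT replicate 2 (0.107) or Utx KO replicate 1 (0.0928) and with DESeq2 (0.115), the lowest of 19 alternatives being 0.00909.

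**Figure D3:**
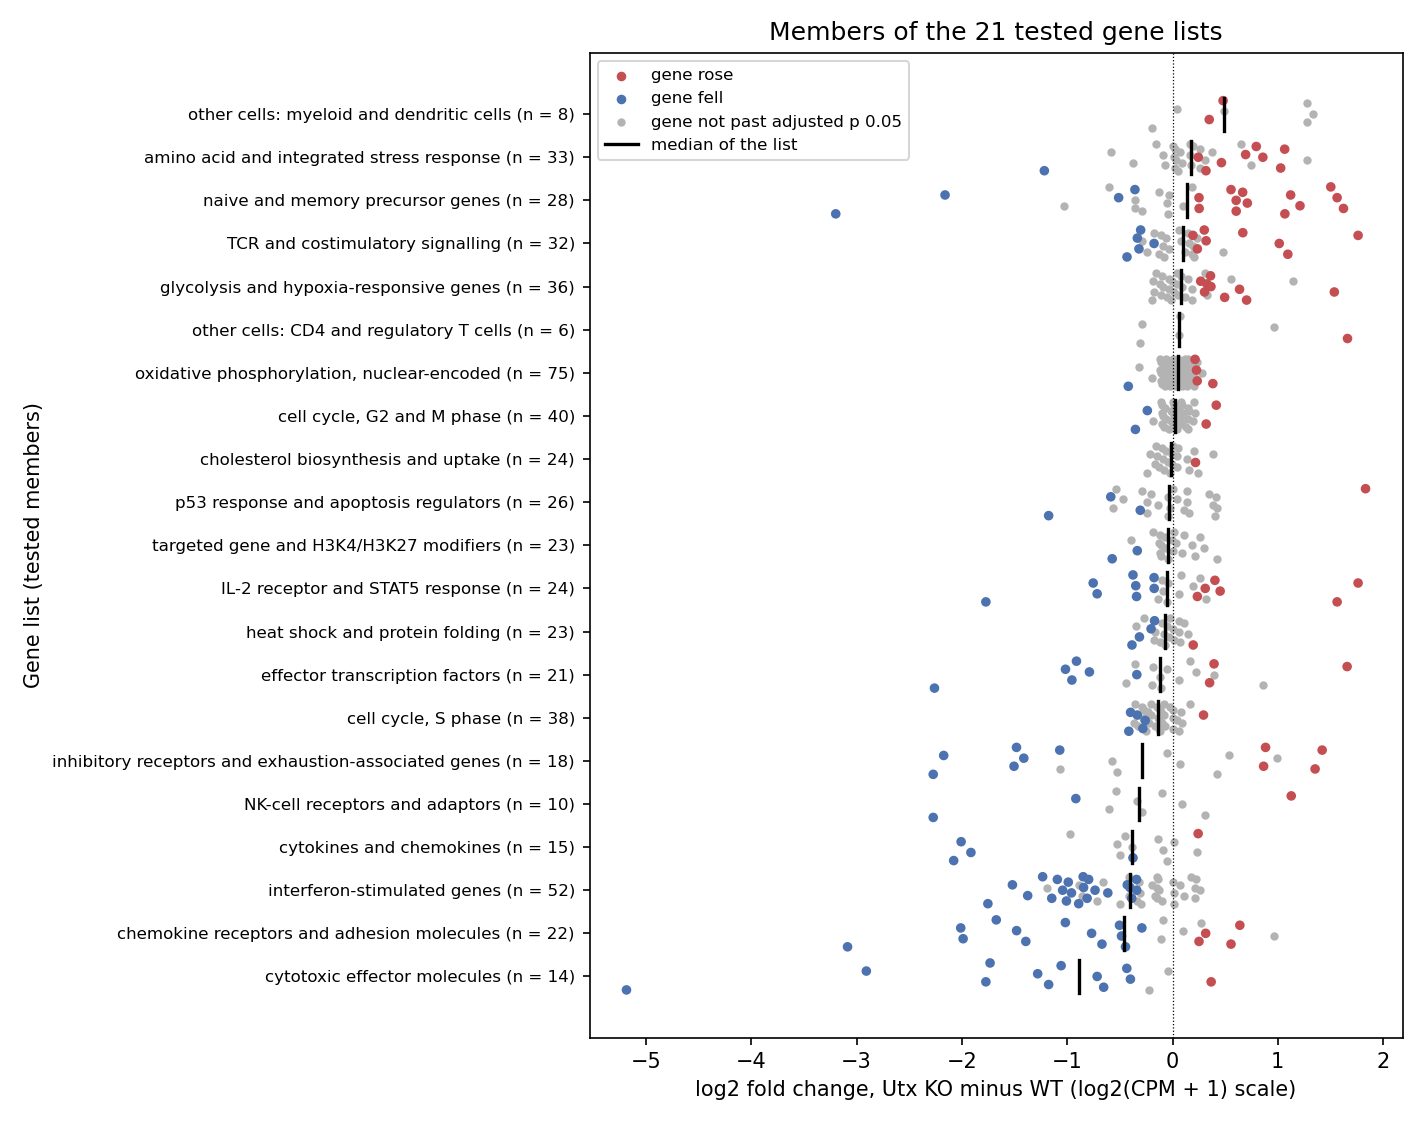
Log2 fold change of Utx KO minus WT (x axis, log2(CPM + 1) scale) of each tested member of 21 gene lists (y axis); red and blue points rose and fell at a limma adjusted p under 0.05, grey points did not pass, and black bars are list medians. Medians run from −0.89 for cytotoxic effector molecules to 0.49 for myeloid and dendritic cell markers.

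Markers of other cell types that the isolation could hold differed in level. Cd4, Lyz2 and S100a8 were listed at 0 in all 6 libraries, while Cd8a was at 257 ± 15.6 CPM in WT and 292 ± 11.8 CPM in Utx KO (SD, n = 3). Others had reads: Cd79b was at 3.93 ± 1.39 and 1.34 ± 0.677 CPM, Csf1r at 1.36 ± 2.02 and 1.24 ± 2.14 CPM, and Cst3 at 71.3 ± 8.17 and 73.5 ± 4.78 CPM in WT and Utx KO. The T-cell receptor constant genes Trac, Trbc1 and Trbc2 were also listed at 0 in these T cells, so a 0 for receptor or immunoglobulin constant genes is not read as absence. Among 8 tested myeloid and dendritic cell markers, 2 rose and 0 fell (5 and 0 adjusted over the list alone). These were Ctss, a lysosomal protease of antigen-presenting cells (56.7 ± 1.99 to 79.8 ± 9.24 CPM), and the MHC class II gene H2-Ab1 (77.7 ± 9.57 to 98.9 ± 6.99 CPM). Camera called the list higher (adjusted p = 0.00543, and adjusted p = 0.326 with an estimated correlation). The call of H2-Ab1 (limma adjusted p = 0.0357) was lost without WT replicate 1 (0.0509), WT replicate 2 (0.235), Utx KO replicate 1 (0.0942) or Utx KO replicate 3 (0.109) and with DESeq2 (0.177), the lowest of 19 alternatives being 0.0170. Markers of CD4 and regulatory T cells gave 1 rise, of Ikzf2, and 0 falls among 6, also when adjusted over the list alone (camera adjusted p = 0.178), and Foxp3 was at 9.35 ± 1.71 and 7.31 ± 0.618 CPM (limma adjusted p = 0.568). Lists with fewer than 5 tested members were not tested. Their summed CPM was 12.6 ± 3.19 in WT and 4.48 ± 2.96 in Utx KO for B-cell markers and 1.48 ± 0.450 and 3.13 ± 1.06 for erythroid and platelet markers. Markers of natural killer and gamma-delta T cells summed to 270 ± 11.5 and 191 ± 12.8 CPM, nearly all of it Eomes, which CD8 T cells also express.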

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

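Of the alternatives below, edgeR with TMM factors, the replicate block in limma, rescaling without mitochondrially encoded (or also ribosomal protein) genes and limma's treat were chosen after seeing the data. Between 754 and 1159 genes changed under 18 of 20 alternatives for the 1142 genes changed in Utx KO against WT. The exceptions were DESeq2 (595) and the stricter threshold, adjusted p under 0.01 (627), which calls fewer by construction. Leaving out each library in turn gave 754 (without WT replicate 2) to 1042 (without Utx KO replicate 1). Among genes called under both settings, 0 changed sign in any alternative. The share of rises ran from 44% (DESeq2) to 55.2% (edgeR, upper-quartile factors). For genes changed at least 2-fold in Utx KO against WT (317), DESeq2 gave 195, and tests against a log2 change of 0.5 gave 127 (limma treat) and 184 (edgeR glmTreat). DESeq2 was run without its own filter on low counts. In the simulation it recovered 30%, 58% and 86.9% of the genes changed 1.5-, 2- and 4-fold, with 0.763% false calls. Limma-trend recovered 40%, 66% and 93.9% there. The cause of the lower DESeq2 counts in the real data was not tested.

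The log2 fold change of Kdm6a in Utx KO against WT was −0.59 with DESeq2 (adjusted p = 0.0708; range over alternatives 0.0056 to 0.0708). It ran from −0.71 to −0.46 when each library was left out.

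With an estimated correlation, camera's adjusted p was 0.326 for cytokines and chemokines, 0.338 for naive and memory precursor genes, 0.134 for effector transcription factors, and 0.0554 each for chemokine receptors and adhesion molecules, interferon-stimulated genes and cell cycle, S phase. It was 0.228 for glycolysis and hypoxia-responsive genes, 0.527 for oxidative phosphorylation, nuclear-encoded, 0.131 for amino acid and integrated stress response, and 0.326 for the list other cells: myeloid and dendritic cells. Their lowest adjusted p over all alternatives ran from 3.08e-17 (interferon-stimulated genes) to 0.0145 (naive and memory precursor genes). The cytotoxic list was past the threshold in each of 21 alternatives (highest adjusted p 0.0150).

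Other settings moved fewer lists. The stricter filter tests fewer genes and gave 0.0791 for cytokines and chemokines, 0.0665 for naive and memory precursor genes and 0.0535 for oxidative phosphorylation, nuclear-encoded. DESeq2 gave 0.112 and 0.0843 for the last 2 of these. With no filter the list other cells: myeloid and dendritic cells had 0.0590. Rescaling without mitochondrially encoded genes gave 0.0647 for oxidative phosphorylation, nuclear-encoded and 0.0487 for heat shock and protein folding. Fry was used to ask whether a list moves in a common direction, without comparing it with other genes. Its adjusted p was 0.0761 for cytokines and chemokines, 0.0653 for naive and memory precursor genes and 0.199 for oxidative phosphorylation, nuclear-encoded. It gave 0.0340 each for inhibitory receptors and exhaustion-associated genes, TCR and costimulatory signalling and other cells: CD4 and regulatory T cells. Leaving out each library gave 0.0145 to 0.0845 for naive and memory precursor genes, 0.00549 to 0.374 for oxidative phosphorylation, nuclear-encoded, 0.0214 to 0.528 for IL-2 receptor and STAT5 response, and 0.00884 to 0.239 for heat shock and protein folding. The cause was not tested.

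Replicates of the same number did not resemble each other more than others: 0 of 6 libraries correlated best with their own number. With the number as a replicate block, 1065 genes changed (302 at least 2-fold) in limma, 1046 of them among the 1142, and 982 (239) in edgeR, with 0 list calls changed.

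Of 95 named genes past the threshold besides Kdm6a, 73 were past it in each alternative that gave a value and 22 lost their call in at least 1. At these depths a count of 0 allows up to 1.19 to 1.85 CPM in a library. The simulation recovered 66% of 2-fold changes over all expression levels together; recovery by level was not tested.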

Other observations

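The gene families, the genes Rps13, Rps15a, S100a6, Sox12 and Serpinb6b and the neighbouring copy Gm4070 were chosen after their values were seen. So were the tests in this part, apart from those set before. The latter are the main limma test of single genes, the camera tests of the myeloid and dendritic list and the counts over other splits of the samples. The families were picked because members had been seen to change, so only their values are given, with no test of the family. Genes of the Wnt and TCF/LEF pathway, of which Lef1, Rnf43, Sox4, Frat2 and Tcf7 are named above, gave 7 rises and 1 fall among 18 tested members (median log2 fold change 0.42). With edgeR, whose filter tests fewer genes, the median was 0.77 to 0.79 over its 3 scalings, with 6 rises and 0 falls. Sox12 rose from 4.63 ± 1.75 to 17.8 ± 2.03 CPM (SD, n = 3). In the Gbp family, which includes Gbp7, Gbp4 and Gbp2 named above, 6 of 10 genes fell and 0 rose (median −0.82). Of 6 S100a genes 4 fell and 1 rose, S100a6 among the falls, from 1042 ± 79.3 to 530 ± 12.7 CPM. All 4 tested Serpinb genes fell, Serpinb6b from 89.1 ± 4.65 to 42.3 ± 1.85 CPM; tubulin genes gave 3 rises and 3 falls among 13. Mitochondrially encoded genes gave 10 falls and 0 rises among 13 (median −0.41) and ribosomal protein genes 48 rises and 2 falls among 80 (median 0.14). The medians of these families kept their direction under each scaling tried, except that of the tubulins, which lies near 0 and turns. A scaling shifts all genes about alike, so a median far from 0 had little room to turn.

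Other splits of the 6 libraries into 3 against 3 were counted in the same way. Each of these mixes the genotypes in both groups, so a difference between genotypes adds to the spread within groups. This lowers their counts of changed genes, which therefore cannot show what chance gives. Of 10 splits, 1, the real one, gave as many changed genes (1142, highest of the others 2). For genes changed at least 2-fold it was again 1 of 10 (317, highest of the others 2). For lists called it was 1 of 10 (11, against 8, 3, 0, 4, 2, 3, 2, 1 and 7 in the others). With the preset correlation, lists were thus also called in most splits that mix the genotypes. With an estimated correlation 1 list was called in the real split, against 0 in each of the others. With 10 splits the share cannot go under 0.05.

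Rps13 and Rps15a, which encode proteins of the small ribosomal subunit and lie on chromosome 7, fell from 2436 ± 3.52 to 764 ± 19.2 CPM and from 1974 ± 44.4 to 943 ± 3.5 CPM (SD, n = 3; log2 fold changes −1.67 and −1.06, limma adjusted p of 1.22e-19 and 8.19e-16). The other 78 ribosomal protein genes argue against a shared fall: their median log2 fold change was 0.15, with 48 rises and 0 falls. A stretch of chromosome 7 that differs between the animals may contribute and stays open. In a window around both genes, 8 of 60 tested genes changed (13.3%), against 10.8% elsewhere (Fisher exact p = 0.528), which does not decide it. The window lies between Gvin1 (chromosome 7, 106156556 to 106215326 in GRCm38) and Apobr (chromosome 7, 126584942 to 126589112) and includes neither. Both of these also fell in Utx KO, so a longer stretch was not tested by this count. Reads shared with processed pseudogenes also stay open. Of the 3' end pieces of Rps13 and Rps15a, 46.3% and 39.5% occur in other gene models, among them pseudogenes named after each gene. Of the pseudogenes so named, 0 are among the genes analysed. The other models that share pieces, such as Gm15483 and Gm11972, were not checked. An effect of the Utx KO itself stays open as well.

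Gvin1 and its neighbour Gm4070, on chromosome 7, varied widely between WT libraries (coefficients of variation 89.0% and 30%). Their sum varied by 2.42%, which fits reads that are split differently between near-identical copies as a candidate explanation, since all 3' end pieces of Gvin1 also occur in Gm4070. A split between Gvin1 and Gm4070 alone does not account for the lower values in Utx KO. Their sum went from 722 ± 17.5 to 333 ± 27.2 CPM (SD, n = 3, log2 fold change −1.12, SE 0.06, limma adjusted p = 6.75e-13). Pieces of the 3' end of Gm4070 also occur in the gene models Gm8979 and Gm8989, which were not part of the sum. The Utx KO, a difference between the animals in the stretch around these genes and reads assigned to those other models all stay open for that fall.

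Of 8 tested myeloid and dendritic cell markers 2 rose in Utx KO, and the list was called higher with the preset correlation (camera adjusted p = 0.00543) but not with an estimated correlation (adjusted p = 0.326) or with no filter (0.0590), the lowest of its alternatives being 0.00094. Cells of another type could be a source, although the isolation kit for CD8 T cells is meant to remove them. More B cells are argued against: the sum of B-cell markers was 4.48 ± 2.96 CPM in Utx KO and 12.6 ± 3.19 CPM in WT (SD, n = 3). Its exact permutation p was 0.1, the smallest possible. Of the 16 listed B-cell markers only 3 were high enough to be tested, and 0 of these changed (2 fell adjusted over the list alone). More monocytes, macrophages or neutrophils in the Utx KO cultures are argued against too, provided their genes were counted: Lyz2, S100a8, S100a9, C1qa, C1qb and C1qc summed to 0 CPM in each library, while Ctss and H2-Ab1 together were 44.3 CPM higher in Utx KO. More dendritic cells stay open: the list without Ctss and the MHC class II genes, most of it Cst3, summed to 84.7 ± 6.34 CPM in Utx KO and 80.5 ± 7.23 CPM in WT (exact permutation p = 0.5), and Itgax, chosen after its values were seen, was at 0 in each Utx KO library. H2-Aa, H2-Eb1 and Cd74 together were at 9.39 ± 3.70 CPM in Utx KO and 2.01 ± 0.960 CPM in WT (exact permutation p = 0.1, the smallest possible); expression by the T cells themselves was not tested.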
